A study of Mus musculus with 6 samples.

How the data were processed

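The data were RNA-seq measurements of mouse CD4+ T cells of the C57BL/6 strain. Per the labels' protocols, the cells were activated through CD3 and CD28 and grown for 5 days with IL-6 and TGF-β, the cytokines that drive naive T cells towards the Th17 state, while IL-4, IFN-γ and IL-2 were blocked with antibodies. The control medium held 200 µM methionine and the restricted medium 3 µM. There were 3 libraries per group. The labels number them but do not say whether they came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

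Per the labels' protocols, cDNA was primed with barcoded oligo-dT, samples were pooled by the qPCR level of Actb, and the libraries keep the strand of the RNA. Such libraries read mainly the 3′ ends of polyadenylated transcripts. STAR, HTSeq and the mouse build mm10 are named in the submitters' processing notes; their versions, the annotation, the strand setting of the counting and the way genes were selected are not given in the sources used here.

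The deposited table holds, for 12336 genes, log2 values of each library and the authors' own comparison. The deposited log2 values were taken as log2(quantile-normalized count + 1), from the values themselves. The 5 highest values were identical in all 6 libraries, the values with the log2 undone summed to between 12415417 and 12415758 per library, and 100% of these values under 30 were whole multiples of a twelfth, to within 0.05 of a twelfth. Quantile normalization gives every library one distribution, so it removes any difference in the total amount of RNA and leaves changes relative to the other genes. It also hides the depth, so library totals are unknown and no counting interval is given. Relative depth shows only in ties. Genes at a library's lowest value numbered 514, 320 and 586 in control replicates 1, 2 and 3, and 650, 298 and 858 in restricted replicates 1, 2 and 3. Below a normalized count of 50 these libraries held 43, 65, 36, 40, 87 and 27 steps in that order, fewer steps meaning fewer reads. Restricted replicate 3, control replicate 3 and restricted replicate 1 were therefore the coarsest for genes of low level. The lowest log2 values of restricted replicates 3 and 1 lay at 0.74 and 0.42, and those of the other libraries at 0.

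The authors' deposited table also gives log2 fold changes, p-values and adjusted p-values, and scores (moderated t and log odds), with control minus restriction as its direction. It calls 896 genes at an adjusted p under 0.05. All values in the report come from a new fit, in the direction restricted minus control.

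A test for counts had been planned before the data were examined. The values are not counts, so the planned replacement was used: limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with the group as the only term, moderated by ordinary empirical Bayes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over 12336 genes. The kind of empirical Bayes moderation had not been fixed for this case. The ordinary kind was taken because its moderated t differed from that in the authors' deposited table by at most 0.00741 and called the same 896 genes; the number of calls with the 3 other kinds (778, 1280 and 1349) was known by then. No filter was added to the one already made in the table. Fold changes are on the log2(value + 1) scale, which understates changes of low genes.

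Lists of genes numbered 39 and were fixed before the data were examined: T helper programmes, methionine and amino acid metabolism, chromatin and nucleic acid methylation, cell cycle, stress, lipid, energy and ribosome genes, markers of other cell types and signs of RNA quality. The 36 lists with at least 5 measured members were tested with camera from limma. It used a preset inter-gene correlation of 0.01 and adjustment over the lists, and was repeated with an estimated correlation and with fry. The estimated correlation was -0.00602 for the amino acid response list and 0.000264 for ribosome biogenesis, both below the preset one. Their adjusted p still rose. These versions of camera therefore differ by more than the correlation. A call lost with an estimated correlation does not by itself show that the genes varied together. Camera asks whether a list moved relative to other genes; fry asks whether its genes moved, on balance, one way. Where 2 identifiers shared a symbol, which happened 3 times, the one with the higher mean was used. Symbols of 19 genes are written as dates in the table, so those genes were used by identifier only.

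Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean in the higher group was at least 20 CPM of the library's normalized total; a fixed panel of 14 genes, of which 13 were analysed here; up to 3 called members per list with the smallest p; and the 2 most abundant members of each list of other cell types or RNA quality. Unnamed and predicted genes were left out of the ranking. Other genes named in the text are members of these lists or are said to have been chosen after their values were seen. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 denotes, matched by stable identifier for 12311 of the 12336 genes; 12265 of these are annotated as protein-coding.

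The fit was tested on simulated data with the levels and spreads of these 12336 genes, 200 µM against 3 µM, in which 50 genes were changed by each of 4 sizes. It recovered 84% of the changes of 4 on the log2 scale, 46% of those of 2, 2% of those of 1 and 0% of those of 0.5, with 10 false calls and 0 calls of the wrong sign. The size of 4 was added after simulated changes of up to 2 had been recovered only in part. On simulated data without any change it made 0 calls. Fewer genes changed in the first simulation than were called in the data, which makes the adjusted threshold stricter. The shares recovered may therefore understate the recovery in the data. Changes of 2-fold or less can still be missed, and a gene that was not called is not shown to be unchanged. Camera called the 1 shifted list of 30 genes among 39 simulated lists, at a shift of 0.5, and 0 of the others. The simulated genes varied independently of each other. This run therefore does not test whether the preset correlation suits genes that vary together.

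The alternatives were a stricter filter (at least 5 CPM of the normalized total in at least 3 libraries, which left 9102 genes), the replicate number as a block, each library left out in turn, an estimated correlation and fry. Added after the data had been seen were a mean-variance trend, robust empirical Bayes, both together, a pseudocount of 10, values under 4 normalized counts raised to 4, centring of each library on its median difference over genes with a mean log2 value of at least 5, and a fit without the genes of the cell cycle lists.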

Results

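The study measured polyadenylated RNA of mouse Th17 cells, the CD4+ T helper cells that make IL-17, after 5 days in medium with 200 µM methionine (control, 3 libraries) or 3 µM methionine (restricted, 3 libraries). Methionine is the precursor of S-adenosylmethionine, the methyl donor of histone, DNA and RNA methylation, and the series title places the comparison in that setting. Values are log2(quantile-normalized count + 1), for which the depth is unknown. Libraries of one group correlated across genes with r between 0.953 and 0.963 and libraries of different groups with r between 0.908 and 0.925; genes are not independent replicates. The first principal component held 50.8% of the variance.

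Methionine restriction lowered transcripts of the cell cycle and part of the Th17 programme and raised genes of the amino acid starvation response. Of 12336 genes, 310 were higher and 586 lower in the restricted libraries (limma, adjusted p under 0.05), which is 7.26% of the genes. At least 2-fold changes were found for 866 of them, 295 higher and 571 lower, and changes of at least 3 on the log2 scale for 53 higher and 203 lower genes. The groups did not overlap for any of the 896 called genes; over all genes this held for 30.6%, against 10% by chance. Among the genes with at least 20 normalized CPM in the higher group, 107 were higher and 312 lower. In 25 of the higher genes all control libraries, and in 50 of the lower genes all restricted libraries, were at their lowest value. No true fold can be given for these genes, and the counts by size of change above do not leave them out. Leaving out any 1 library reduced the higher genes to between 135 (without restricted replicate 1) and 175 (without control replicate 3), and the lower genes to between 350 (without control replicate 1) and 414 (without restricted replicate 3). The higher genes numbered between 528 and 577 with a mean-variance trend and 548 with a pseudocount of 10.

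**Figure D1:**
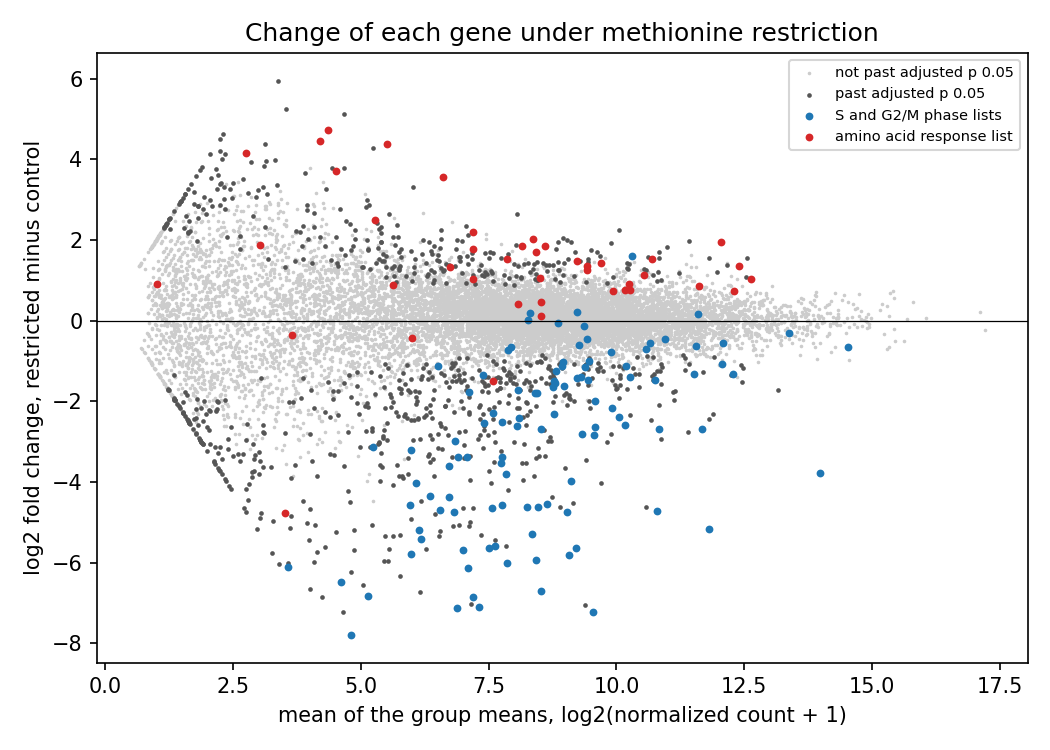
Log2 fold change (restricted minus control, y axis) of each of 12336 genes against the mean of the group means in log2(normalized count + 1) (x axis). Genes of the S and G2/M phase lists (blue) lie mostly below 0, with 75 of 105 called lower, and genes of the amino acid response list (red) lie mostly above 0, with 19 of 42 called higher.

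The signature cytokine of the cells fell. Il17a (ENSMUSG00000025929.4, chromosome 1, 20730905 to 20734496 on the plus strand, GRCm38) had a log2 value of 12.78 ± 0.29 (SD, n = 3) in control and 10.01 ± 0.32 (SD, n = 3) in restricted libraries, a log2 fold change of -2.77 (SE 0.27, limma adjusted p = 0.00273). Ccr6, the chemokine receptor carried by Th17 cells, fell by 4.61 (SE 0.26, adjusted p = 0.000635) and its ligand gene Ccl20 had a log2 fold change of -2.94 and was called too. Tmem176a and Tmem176b, ion channel genes, fell as well, with log2 fold changes of -3.52 and -3.05. Il9 fell from 4.84 ± 0.12 to 0.68 ± 0.24 (SD, n = 3 each), with 2 of 3 restricted libraries at their lowest value; its log2 fold change of -4.17 became -2.52 when values under 4 normalized counts were raised to 4. Il17f had a log2 fold change of -0.66 (SE 0.32, adjusted p = 0.271) and Il23r, the receptor for IL-23, of -0.10 (SE 0.31, adjusted p = 0.876); neither passed the threshold. Other genes of the list rose. Il12rb1, a receptor chain shared by IL-12 and IL-23, rose by 1.96 (SE 0.21, adjusted p = 0.00385). Il22 (chromosome 10, 118204942 to 118210047) rose from 2.12 ± 1.85 to 7.24 ± 0.07 (SD, n = 3 each), a log2 fold change of 5.12 (SE 0.86, adjusted p = 0.0215) that was 4.34 with low values raised to 4. Control replicate 2 was at its lowest value for Il22. The fold change was 5.77 without control replicate 1 and 4.06 without control replicate 2, and the adjusted p was 0.0712, 0.0707 and 0.0669 without restricted replicate 1, 2 or 3. Over the 31 measured genes of the Th17 list, 7 fell, 3 rose and 21 did not pass the test; adjusted over the list alone, 10 fell and 6 rose. Without any 1 library, 1 or 2 rose. The median log2 fold change was -0.28 (camera adjusted p = 0.0144). The call was lost with an estimated correlation (adjusted p = 0.489) and with a stricter filter on low values (adjusted p = 0.0624). Of 15 myeloid markers 3 fell in the same libraries, and the call of that list was lost with an estimated correlation (adjusted p = 0.432). Of 4 red cell and platelet markers 2 fell, Pf4 and Ppbp, and the median of the 4 was -2.46. The Pf4 call was lost without any 1 control library or restricted replicate 2 or 3 (adjusted p up to 0.0929).

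**Figure D2:**
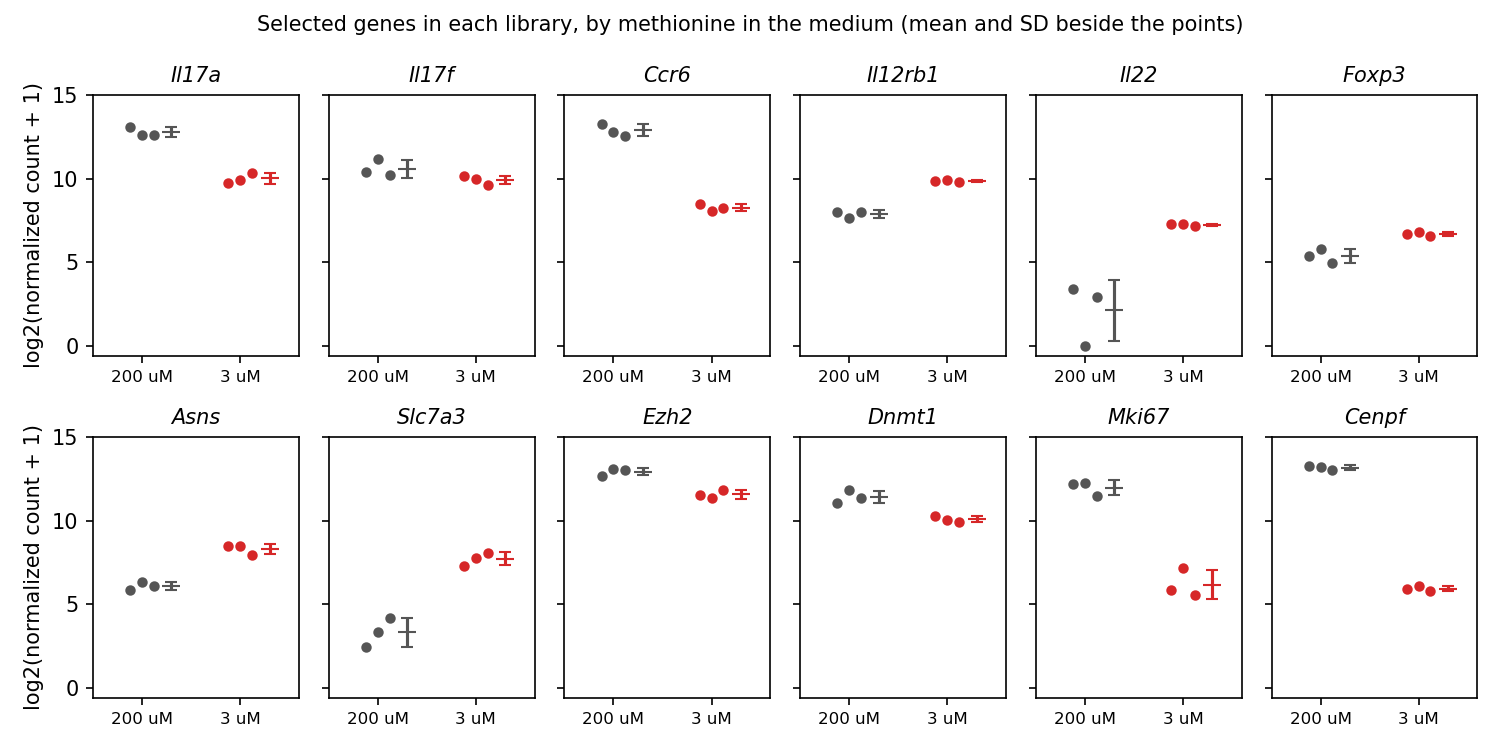
Log2(normalized count + 1) (y axis) of 12 genes in each library of the control (grey, 200 µM) and restricted (red, 3 µM) groups, with the mean and SD of 3 libraries beside the points. Il17a, Ccr6, Mki67 and Cenpf are lower and Il22, Asns and Slc7a3 higher in all restricted libraries, while the groups overlap for none of these 7 genes.

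Genes of other T helper states changed in both directions. Of 19 regulatory T cell genes, 1 rose and 2 fell (3 and 2 adjusted over the list alone). Itgae, the integrin CD103, fell by 3.41 (SE 0.24, limma adjusted p = 0.00098) and Ikzf4, the transcription factor Eos, fell by 1.67 (SE 0.21, adjusted p = 0.00763). Foxp3, the lineage factor, rose by 1.33 (SE 0.27, adjusted p = 0.0386); it missed the threshold without control replicate 1 or 3 or restricted replicate 1, 2 or 3, with an adjusted p of up to 0.12. The list as a whole was not called (camera adjusted p = 0.843, upward, with a median of 0.18 and a mean of -0.01; fry gave a downward direction, adjusted p = 0.476). Of 18 Th1 genes, Il18r1, a chain of the IL-18 receptor, fell by 2.16 (SE 0.21, adjusted p = 0.00299) and Eomes rose by 2.60 (SE 0.52, adjusted p = 0.0375), or by 1.75 with low values raised to 4. Eomes missed the threshold without control replicate 1 or 2 or any 1 restricted library (adjusted p up to 0.106). Adjusted over the list alone 1 Th1 gene rose and 2 fell. Ifng had a log2 fold change of 0.94 (SE 0.60, adjusted p = 0.392), which was 0.23 without control replicate 2. The Th1 list was not called (adjusted p = 0.843); its median of 0.02 and mean of 0.05 lay above 0 while camera gave a downward direction. Of 9 Th2 genes, 1 rose, Il4ra, by 0.98 (SE 0.21, adjusted p = 0.0435; 1 rose and 1 fell adjusted over the list alone). Il4ra missed the threshold without any 1 of the 6 libraries (adjusted p up to 0.117), and the list was not called (adjusted p = 0.9). None of the 18 naive and memory T cell genes passed, and 3 had an unadjusted limma p under 0.05 (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.905, with a median of -0.05 and an upward camera direction). Among 24 activation and checkpoint genes 3 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.277; fry upward, adjusted p = 0.0438). Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, fell by 1.02 (SE 0.20, adjusted p = 0.0338) and missed the threshold without any 1 library (adjusted p up to 0.11). Those that rose were the orphan nuclear receptor gene Nr4a2, by 2.25 (SE 0.22, adjusted p = 0.00272), the early activation marker Cd69, by 1.75 (SE 0.24), and the immediate early gene Egr1, by 1.59 (SE 0.22).

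Genes of the amino acid response, which the transcription factor ATF4 drives when amino acids run short, rose together. Of 42 measured genes 19 rose, 1 fell and 22 did not pass, and 38 had a positive fold change; adjusted over the list alone 31 rose and 2 fell. Without any 1 library the 19 became between 7 (without control replicate 2) and 12 (without control replicate 1). The median log2 fold change was 1.35, with a camera adjusted p of 2.68e-12 that stayed under the threshold with an estimated correlation (adjusted p = 0.0115). Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254), rose from 6.10 ± 0.23 to 8.30 ± 0.29 (SD, n = 3 each), by 2.20 (SE 0.25, limma adjusted p = 0.00474). Slc7a3, a transporter of cationic amino acids, rose by 4.39 (SE 0.47, adjusted p = 0.00398), and Trib3, a pseudokinase induced by ATF4, by 3.57 (SE 0.48, adjusted p = 0.00934). Soat2, an enzyme of cholesterol ester formation, rose by 4.15, or by 2.52 with low values raised to 4. Ddit3, which encodes CHOP, had a log2 fold change of 0.73 (SE 0.23, adjusted p = 0.117). Vldlr, a lipoprotein receptor, was the member that fell, at a log2 fold change of -4.75 (SE 0.54), with 2 of 3 restricted libraries at their lowest value, or of -3.58 with low values raised to 4.

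Genes that supply and charge amino acids rose in part. Of 23 amino acid transporters 4 rose and 0 fell (8 and 2 adjusted over the list alone; between 2 and 4 rose without any 1 library; camera adjusted p = 0.2; fry upward, adjusted p = 0.0435). Slc1a4, a transporter of neutral amino acids, rose by 2.00 (SE 0.28, limma adjusted p = 0.0113). Slc7a5, the large neutral amino acid transporter that carries methionine, rose by 1.84 (SE 0.36, adjusted p = 0.0348); it missed the threshold without control replicate 2 or 3 or any 1 restricted library (adjusted p up to 0.101). Of 20 cytosolic tRNA synthetases 4 rose, 1 or 2 without any 1 library and 10 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 6.62e-05). That call was lost with an estimated correlation (adjusted p = 0.108). Yars rose by 1.53 (SE 0.19, adjusted p = 0.00673), whereas Cars and Aars, at 1.70 and 0.92, missed the threshold without any 1 library (adjusted p up to 0.123 and 0.131). Of 19 serine and one-carbon genes 6 rose and 2 fell (8 and 3 adjusted over the list alone); 3 rose without restricted replicate 1 and 2 without any other 1 library. Camera did not call the list (adjusted p = 0.0572) and fry called it upward (adjusted p = 0.0304). Aldh1l2, a mitochondrial formyltetrahydrofolate dehydrogenase, was at the lowest value in 3 control libraries and at 4.50 ± 0.76 (SD, n = 3) in restricted libraries. Tyms, which makes thymidylate and is also induced in dividing cells, fell by 2.60 (SE 0.27).

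Of 19 measured genes of the methionine cycle and its salvage 2 rose and 0 fell (3 rose adjusted over the list alone), and 17 had a positive fold change. Camera did not call the list (adjusted p = 0.0572) and fry called it upward (adjusted p = 0.00895). Without any 1 library 0 or 1 rose. Mettl16, an RNA methyltransferase, rose by 1.70 (SE 0.38, limma adjusted p = 0.0496) and missed the threshold without any 1 library (adjusted p up to 0.142). Ahcy, which clears S-adenosylhomocysteine, had a log2 fold change of 0.01 (SE 0.27, adjusted p = 0.986). Of 14 polyamine genes 0 passed, also when adjusted over the list alone, and 4 had an unadjusted limma p under 0.05 (camera adjusted p = 0.266; fry adjusted p = 0.14). Of 26 transsulfuration and glutathione genes 2 rose, both also adjusted over the list alone (camera adjusted p = 0.766). These were Chac1, a glutathione-degrading enzyme, by 4.45 (SE 0.92, adjusted p = 0.0415), and Mpst, by 2.78 (SE 0.51, adjusted p = 0.028), or by 3.57 and 1.42 with low values raised to 4. Chac1 was 5.43 and 3.45 without control replicates 1 and 2, and missed the threshold without control replicate 3 or any 1 restricted library (adjusted p up to 0.113). Mpst missed it without control replicate 2 or any 1 restricted library (adjusted p up to 0.0787).

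Enzymes that write histone methylation changed in both directions. Of 42 histone methyltransferase genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; 0 or 1 rose without any 1 library), with a median of 0.08. Camera did not call the list (adjusted p = 0.629) and fry called it upward (adjusted p = 0.0318). Ezh2, the H3K27 methyltransferase (chromosome 6, 47530139 to 47595341), fell by 1.36 (SE 0.23, limma adjusted p = 0.0225). Whsc1, an H3K36 methyltransferase, fell by 1.33 (SE 0.21, adjusted p = 0.0163), and Smyd5 rose by 1.40 (SE 0.21, adjusted p = 0.0134). Ezh2 missed the threshold without control replicate 2 or 3 or restricted replicate 1 or 2, and Whsc1 without control replicate 1 or 3 or restricted replicate 1 or 2 (adjusted p up to 0.0771 and 0.0641); Smyd5 missed it without control replicate 3 (adjusted p = 0.0505). Of 21 histone demethylases 1 rose, also when adjusted over the list alone (camera adjusted p = 0.297). It was the H3K27 demethylase Kdm6b, by 1.01 (SE 0.20, adjusted p = 0.0374), which missed the threshold without any 1 library (adjusted p up to 0.106). Of 23 genes of DNA and RNA methylation 1 rose and 2 fell (3 and 2 adjusted over the list alone; 0 rose and 1 fell without any 1 library; camera adjusted p = 0.127; fry upward, adjusted p = 0.0435). Uhrf1, which brings the maintenance methyltransferase to replicated DNA and is also in the cell cycle lists, fell by 2.69 (SE 0.27, adjusted p = 0.00317). Dnmt1, that methyltransferase, fell by 1.33 (SE 0.26, adjusted p = 0.0348) and missed the threshold without any 1 library (adjusted p up to 0.11). Of 15 phospholipid methylation genes 0 passed, also when adjusted over the list alone, and 2 had an unadjusted limma p under 0.05 (camera adjusted p = 0.843).

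The deepest falls were in genes of cell division. Of 56 G2/M phase genes 46 fell and 1 rose (51 and 1 adjusted over the list alone), with a median log2 fold change of -4.18 (camera adjusted p = 7.18e-44). Of 49 S phase genes 29 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -1.61 (camera adjusted p = 3.47e-25). Both calls held with an estimated correlation (adjusted p = 0.00217 and 0.00586). Cenpf, a kinetochore protein gene (chromosome 1, 189640606 to 189688086), fell from 13.16 ± 0.14 to 5.93 ± 0.15 (SD, n = 3 each), a log2 fold change of -7.23 (SE 0.20, limma adjusted p = 0.000158). The proliferation marker Mki67 fell by 5.80 (SE 0.48, adjusted p = 0.00168). Hmmr, the cyclin gene Ccnb2, the checkpoint gene Clspn and the ribonucleotide reductase gene Rrm2 had log2 fold changes of -7.09 (SE 0.35), -5.68 (SE 0.27), -6.71 (SE 0.40) and -4.54 (SE 0.32) and were called as well. The genes of both lists made up 12.8% of all lower genes. Of 24 p53 and apoptosis genes 3 rose and 1 fell (8 and 1 adjusted over the list alone; 0 or 1 rose without any 1 library; camera adjusted p = 0.127). Pmaip1, which encodes the death protein NOXA, fell by 2.15 (SE 0.21, adjusted p = 0.00273). Aen and Zmat3 rose by 1.39 and 1.55 and missed the threshold without, for Aen, control replicate 1 or 3 or any 1 restricted library and, for Zmat3, any 1 library (adjusted p up to 0.0853 and 0.0917). Of 15 myeloid markers 3 fell in the same libraries, and the call of that list was lost with an estimated correlation (adjusted p = 0.432). Of 4 red cell and platelet markers 2 fell, Pf4 and Ppbp, and the median of the 4 was -2.46. The Pf4 call was lost without any 1 control library or restricted replicate 2 or 3 (adjusted p up to 0.0929).

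Genes of ribosome production shifted upward by small amounts. Of 57 genes of ribosome biogenesis and MYC 4 rose and 0 fell, 13 rose adjusted over the list alone and between 0 and 2 without any 1 library, and 52 had a positive fold change. The median was 0.62 (camera adjusted p = 1.48e-07; adjusted p = 0.0197 with an estimated correlation). Ppan rose by 1.13 (SE 0.19, limma adjusted p = 0.021) and Rrp12 by 1.03 (SE 0.20, adjusted p = 0.034), and both missed the threshold without any 1 library (adjusted p up to 0.0718 and 0.112). Of 78 cytosolic ribosomal protein genes 2 rose, 0 adjusted over the list alone, and 69 had a positive fold change, with a median of 0.31 (camera adjusted p = 0.000597). That call was lost with an estimated correlation (adjusted p = 0.663) and with fry (adjusted p = 0.119). Ribosomal protein genes have many pseudogene copies, so reads shared with copies make their values uncertain. The 2 that rose, Rpl15 and Rpl21, by 1.24 and 1.18, missed the threshold without any 1 library (adjusted p up to 0.0746 and 0.131).

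Lipid and glycolysis genes fell in part. Of 24 cholesterol synthesis genes 3 fell, 6 adjusted over the list alone, 3 without restricted replicate 3 and 0 without any other 1 library, and 23 had a negative fold change, with a median of -0.52 (camera adjusted p = 3.77e-06; adjusted p = 0.262 with an estimated correlation). Insig1, Hsd17b7 and Hmgcs1 fell by 1.32, 1.37 and 1.25; each missed the threshold without any 1 control library or restricted replicate 1 or 2 (adjusted p up to 0.0929, 0.116 and 0.118). Of 19 fatty acid synthesis genes 2 fell, both also adjusted over the list alone (camera adjusted p = 0.249; fry downward, adjusted p = 0.0069). The desaturase gene Fads2 fell by 3.60 (SE 0.20, limma adjusted p = 0.000635). Scd2 fell by 2.17 (SE 0.36, adjusted p = 0.0198) and missed the threshold without any 1 control library or restricted replicate 2 (adjusted p up to 0.0647). Of 34 glycolysis and hypoxia genes 5 fell and 1 rose (6 and 2 adjusted over the list alone; 2 fell without any 1 library; camera adjusted p = 0.0788). Bnip3, a mitophagy receptor induced in hypoxia, fell by 2.82 (SE 0.32, adjusted p = 0.00498) and the lactate exporter gene Slc16a3 by 1.92 (SE 0.24, adjusted p = 0.00749). Ndrg1 rose by 1.36 and missed the threshold without any 1 library (adjusted p up to 0.0728). Of 19 TGF-β response genes 2 fell, 3 adjusted over the list alone (camera adjusted p = 0.139; fry downward, adjusted p = 0.0138): Itgae, given above, and the receptor gene Tgfbr1, at a log2 fold change of -1.6 (SE 0.24, adjusted p = 0.0151). Tgfbr1 missed the threshold without control replicate 2 or 3 (adjusted p = 0.0555 and 0.054).

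Among the genes with at least 20 normalized CPM, the 8 largest rises were Trib3, Zfp948, Pyhin1, Nr4a2, Asns, Chst15, Slfn5 and Cebpb, with log2 fold changes from 3.57 down to 2.04. Zfp948 missed the threshold without any 1 restricted library (adjusted p up to 0.0815). Pyhin1 and Slfn5 missed it without control replicate 1 or 3 or restricted replicate 1 or 2 (adjusted p up to 0.0943 and 0.123), and Cebpb without control replicate 2 or 3 (adjusted p = 0.0574 and 0.0524). The 8 largest falls were Kif2c, Cenpf, Mxd3, Ube2c, Hmmr, Esco2, Ccna2 and E2f8, from -7.79 to -6.84. With low values raised to 4, Kif2c was at -6.38, Mxd3 at -5.95 and E2f8 at -6.20. Leaving out restricted replicate 1 moved Ube2c to -6.46, E2f8 to -6.19 and Esco2 to -7.67, leaving out restricted replicate 2 moved Esco2 to -6.02, and leaving out restricted replicate 3 moved Kif2c to -8.49 and Ccna2 to -6.12.

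Markers of other cell types were measured in the same libraries. Of 15 myeloid markers 3 fell and 0 rose, 5 and 0 adjusted over the list alone and between 0 and 2 fell without any 1 library, with a median log2 fold change of -0.83 (camera adjusted p = 0.0046; adjusted p = 0.432 with an estimated correlation). The most abundant were Cst3, with log2 values of 10.05 ± 0.38 in control and 10.42 ± 0.38 in restricted libraries (SD, n = 3 each; limma adjusted p = 0.508), and Lyz2, lysozyme, which fell from 10.08 ± 0.17 to 8.0 ± 0.62, a log2 fold change of -2.08 (SE 0.34, adjusted p = 0.0198). Lyz2 missed the threshold without any 1 control library or restricted replicate 2 (adjusted p up to 0.0651). The list of red cell and platelet markers had 4 measured genes, too few for the list test; 2 fell, 3 adjusted over the list alone. The platelet gene Pf4 fell from 8.16 ± 0.76 to 2.81 ± 2.07 (SD, n = 3 each), a log2 fold change of -5.35 (SE 1.02, adjusted p = 0.0322), and missed the threshold without any 1 control library or restricted replicate 2 or 3 (adjusted p up to 0.0929). The Pf4 fold change was -4.15 without restricted replicate 1 and -5.97 without restricted replicate 3, and -4.71 with low values raised to 4. Ppbp, another platelet gene, had a log2 fold change of -3.43 (SE 0.27, adjusted p = 0.00153) and stayed called without any 1 library (adjusted p up to 0.0103). For Ppbp 2 of 3 restricted libraries were at their lowest value, and the fold change was -1.69 with low values raised to 4. Itga2b had a log2 fold change of -1.50 (SE 0.53, adjusted p = 0.155), and of -0.87 without restricted replicate 3. Of 7 CD8 T cell markers 0 passed and 3 had an unadjusted limma p under 0.05; adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.843; median -0.02, mean 0.01). Crtam and Prf1 were at -0.49 (adjusted p = 0.222) and 0.03 (adjusted p = 0.963). Of 7 B cell markers 0 passed, also when adjusted over the list alone, and 1 had an unadjusted limma p under 0.05 (camera adjusted p = 0.829; median 0.19, mean -0.13 and a downward camera direction). Ebf1 was at -2.17 (adjusted p = 0.0944), and at -1.64 (adjusted p = 0.0323) with low values raised to 4; it was at -1.51 without restricted replicate 3. Jchain was at -0.19, and at 0.41, 0.46 and -0.82 without control replicate 3, restricted replicate 2 and restricted replicate 3. The 3 measured NK, innate lymphoid and γδ T cell markers, too few for the list test, did not pass, and 0 had an unadjusted limma p under 0.05; Klre1 and Zbtb16 were at -0.81 and -0.45. Klre1 was at -1.51 without control replicate 2 and at -0.18 without restricted replicate 3, where Zbtb16 was at 0.04.

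RNA quality lists were not called. Of 9 mitochondrial transcripts 0 passed, also when adjusted over the list alone, and 1 had an unadjusted limma p under 0.05 (camera adjusted p = 0.266), with mt-Nd1 at 0.08 and mt-Nd4 at -0.50. Of 18 immediate early and heat shock genes 1, Egr1, rose and 1, Hspa1a, fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.358), with Hsp90aa1 at 0.06 and Hspa8 at -0.07. Hspa1a fell by 1.97 (SE 0.35, adjusted p = 0.024), which was -1.0 with low values raised to 4. It missed the threshold without control replicate 1 or 3 or restricted replicate 1 or 2 (adjusted p up to 0.0776), with a mean-variance trend and with a pseudocount of 10. The list of noncoding nuclear RNAs was not analysed here. No gene passed, over all genes or adjusted over the list alone, among 73 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.216), 27 of the unfolded protein response (camera adjusted p = 0.843), 33 of autophagy and lysosomes (camera adjusted p = 0.266), 41 of the interferon response (camera adjusted p = 0.249) and 31 of the proteasome (camera adjusted p = 0.843). An unadjusted limma p under 0.05 was found for 4, 6, 5, 7 and 1 of these genes, in that order. Over the 36 lists tested 9 were called, 4 upward and 5 downward, and 4 of the 9 held with an estimated correlation: G2/M phase, S phase, amino acid response and ribosome biogenesis.

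**Figure D3:**
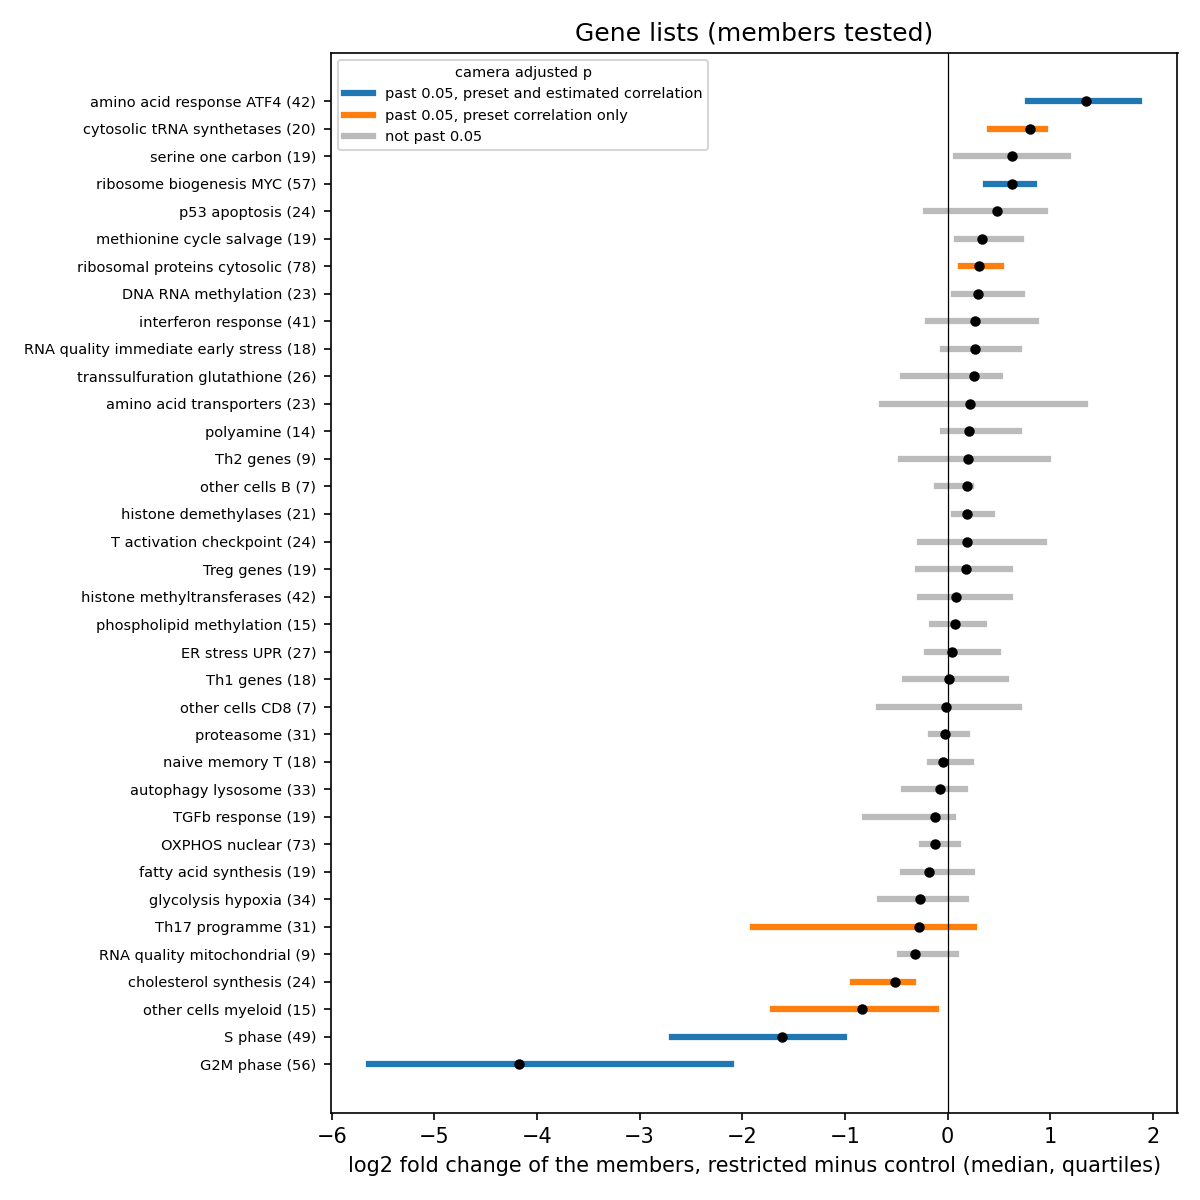
Median (point) and quartiles (bar) of the log2 fold changes (x axis, restricted minus control) of the members of 36 gene lists, with the number of measured members in brackets. The G2/M phase list lies lowest, at a median of -4.18, and the amino acid response list highest, at 1.35; blue bars are called with both correlations, orange bars with the preset one, grey bars with neither.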

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

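The mean-variance trend, robust moderation, the pseudocount of 10, the raised low values, the centring and the fit without cell cycle genes were chosen after the data had been seen. Alternatives chosen before the data were examined that need counts (other size factors, plain library totals, thinning to one depth, and count models) were not run, since the values are not counts; the table was already filtered, so a fit without a filter is the reported one, and the reported fit is already the non-robust one. With fewer libraries the counts of calls fell. Leaving out 1 library gave between 135 and 175 higher genes, between 350 and 414 lower genes and between 500 and 586 genes changed at least 2-fold; between 444 and 501 of the 896 reported genes stayed called and none of them changed sign. The higher genes numbered 528 with a mean-variance trend, 577 with a trend and robust moderation, and 548 with a pseudocount of 10, against 310 as reported; the cause was not tested. The other counts of higher genes, lower genes and genes changed at least 2-fold, with all 6 libraries and without a block, stayed within 1.5 times of those reported. Counts within lists moved more: of the ribosome biogenesis genes 4 rose as reported, 13 with the stricter filter and 14 with the trend. Centring gave 262 higher and 636 lower genes.

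The labels do not say that replicate numbers pair, so a fit without a block had been planned before the data were examined. Deviations from the group means correlated weakly between samples with the same replicate number, at -0.00045, 0.0895 and 0.078. Between samples with different numbers these correlations ran from -0.118 to 0.0398. With the replicate number as a block, which leaves fewer residual degrees of freedom, 125 genes were higher, 343 lower and 468 changed at least 2-fold, and 9 lists were called; 28 of the named genes passed the threshold only without the block. Only restricted replicate 2 and control replicate 2, and restricted replicate 3 and control replicate 3, correlated best with their own number; control replicate 1 and restricted replicate 1 did not, at most 0.0398 with another number.

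Camera called 4 lists with an estimated correlation and fry called 16, against 9. With each library left out between 9 and 12 lists were called. Of the 75 named genes that were called, all 75 kept their sign and 38 also kept their call in each alternative that tested them (the stricter filter and the fit without cell cycle genes left some out); without 1 library, between 24 and 33 lost it. The depth is unknown, and the simulated data recovered 46% of changes of 2 and 2% of changes of 1 on the log2 scale, so small changes cannot be excluded for genes that were not called.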

Other observations

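The tests below were chosen after the results they bear on had been seen, except the counts over other splits of the libraries. Families of genes that share a symbol stem or a receptor were looked at after the comparison had been seen, 43 in all. Camera called 6 of them with the preset correlation and 0 with an estimated one. For the Cenp family the estimated correlation was -0.0172, below the preset 0.01, so a larger correlation does not explain its higher adjusted p. Of 19 genes with the stem Cenp, mostly centromere proteins, 11 fell and 0 rose, with a median log2 fold change of -2.71 (adjusted p = 1.15e-10; adjusted p = 0.069 with an estimated correlation), and 3 of the 19 are also in the cell cycle lists. Cenpe, a kinetochore motor, fell by 4.71 and Cenpa, the centromeric histone, by 2.82. Of 29 genes with the stem Kif, kinesins but for the binding protein Kif1bp, 11 fell (adjusted p = 5e-06; adjusted p = 0.373 with an estimated correlation), and of 11 genes with the stems Pola, Pold or Pole 3 fell, where Poldip2 and Poldip3 are interacting proteins and the others subunits of DNA polymerases (adjusted p = 0.00311; adjusted p = 0.288 with an estimated correlation). Among 362 genes with the stems Zfp, Zbtb or Zkscan, mostly zinc finger genes, 265 had a positive fold change and the median was 0.33, but 9 rose and 2 fell (adjusted p = 0.00234; adjusted p = 0.069 with an estimated correlation). Of 24 genes with the stems Utp, Nop or Rrp, most of them of rRNA processing, 3 rose (adjusted p = 0.0101; adjusted p = 0.364 with an estimated correlation).

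With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, at least 310 genes were higher, and the same held for 586 lower genes and for 866 genes changed at least 2-fold; the highest of the other splits called 0 with limma, and these had between 250 and 787 genes at an unadjusted p under 0.05. For lists, 2 of the 10 splits gave at least the 9 of the real split, and the others gave between 3 and 11. Every other split puts libraries of both groups on each side. Part of the difference between the groups therefore stays in such a split, and part enters its spread. The counts of the other splits, of genes and of lists alike, thus do not measure chance, and no conclusion is drawn from them.

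The fall of the S and G2/M phase genes was set against a difference in depth or quantile normalization and against the loss of cells of another type. In 10000 random lists matched on mean value the median of their medians was 0.0758, and 95% of them lay between -0.04 and 0.19. The 105 cycle genes had a median of -2.60 and so fell beyond other genes of like level. Quantile normalization tends to keep the medians of matched lists small in any case. The matched lists alone therefore cannot exclude an effect of depth or normalization on the cycle genes themselves. Without restricted replicate 3, the coarsest library, the median was -4.27 for the G2/M and -1.59 for the S phase list. With low values raised to 4 the medians were -4.162 and -1.615. Quantile normalization keeps the order of genes within a library. These values argue against depth or normalization as the source of the fall of both lists relative to other genes. Over 32 markers of CD8 T, B, myeloid, NK and γδ T cells the median was -0.416, with quartiles of -1.04 and 0.20, which argues against a loss of those cells as the whole cause. A loss of red cell precursors or platelets cannot be told apart: their 4 markers had a median of -2.46, with quartiles of -3.91 and -0.92 and 1 of 4 positive, and are too few to decide. In control libraries Pf4 and Itga2b were at 8.16 and 5.98, below Cenpf and Mki67 at 13.16 and 11.97. The G2/M gene Cdc25c lay between Pf4 and Itga2b, at 6.63. Such levels do not give the share of a cell type, so they do not decide it. Cell types outside the lists were not examined. Of the members, 59.2% fell in the S phase list and 82.1% in the G2/M phase list. That fewer cells were cycling under methionine restriction by day 5 is a candidate explanation, found and tested on the same data. It stays open beside those left undecided above.

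The fall of myeloid and platelet markers was set against a lower share of such cells. The list's median lay at percentile 0.32 of random lists matched on mean value, so the list fell beyond other genes of like level. As above, such lists cannot exclude an effect of depth or normalization on these genes. Among the 7 markers with a mean log2 value of at least 6, Lyz2 and Cst3 differed by 2.45 (SE 0.458). This cannot be told apart from a smaller share of myeloid cells, since T cells may express Cst3 at a level that would hide it. A change of these genes within the T cells also stays open. The labels name CD4+ T cells but no purity.

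Il22 rose, and Cyp1a2, chosen after its values were seen, was at the lowest value in 3 control libraries and at 4.13 ± 0.62 (SD, n = 3) in restricted libraries. Both genes are known targets of the aryl hydrocarbon receptor, so a shared rise of its targets was tested as a hypothesis over the other 5 targets measured. Their median log2 fold change was 0.997, 4 of 5 were positive and Cyp1b1 and Tiparp were called; camera gave p = 0.00284 with the preset correlation and p = 0.0833 with an estimated one. Cyp1b1 rose by 1.38 and Tiparp by 1.37; Cyp1b1 missed the threshold without control replicate 1 or 2 or restricted replicate 2 or 3, and Tiparp without any 1 control library or restricted replicate 1 or 3 (adjusted p up to 0.0606 and 0.0949). Cyp1a1 and Ahrr were at 0.997 and 0.82 (adjusted p = 0.0585 and 0.0893), and Nqo1 was at -0.17, or at 0.46 and -0.99 without restricted replicates 1 and 3. Cyp1a1 passed in some alternatives, such as with low values raised to 4 (adjusted p = 0.0428). With all 6 targets other than Il22, the family was 1 of the 43 looked at (camera adjusted p = 0.00234, or 0.373 with an estimated correlation). These 6 include Cyp1a2, whose rise prompted the hypothesis, so the family result is not separate support for it. The result may reflect receptor activity. These libraries do not decide it, since the 5 genes are few and the p depends on the version of camera used.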
